A study of Mus musculus with 23 samples.

How the data were processed

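Total RNA of the hypothalamus of male db/db mice was hybridised, per the labels, to 23 Affymetrix whole-transcript mouse arrays, 1 per sample. The mice were 8 weeks old, had been on chow for 2 weeks, and received celastrol or DMSO (25 µl per day) by intraperitoneal injection; the celastrol dose is given as 250 µg/kg at 6 h, and a dose for the later times is not given in the sources used here. The groups come from the labels: vehicle and celastrol at 6 h, 1 day and 4 days, with 4 arrays each except 3 for celastrol at 6 h. The deposited values are log2 expression values per probe set, made by the authors with RMA, per the submitters' processing notes. The software, its version, the arrays normalised together and any filter are not given in the sources used here. The values were used as deposited, with no further normalisation, since array medians lay between 8.57 and 8.64.

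Probe sets were named through the annotation table of the array, with symbols updated by gene identifier. Of 23492 probe sets, 20228 named 1 gene (20184 under a current symbol, 44 under the table's older symbol), 1399 named several and 1865 named none. Control probe sets were left out and only probe sets naming 1 gene were used; for the 811 genes with more than 1, the probe set with the highest mean over all arrays was taken. This left 18702 genes, tested with no filter on level. Il1r1, Agrp and Hspa1b had been chosen for report but had no probe set of their own in the table and were not analysed here. No coordinates are given, since no genome build was used.

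Differences were tested with limma 3.58.1 in R 4.3.3. A model of 6 group means was fitted to all 23 arrays, so that the groups share an estimate of each gene's spread (17 residual and 5.424 prior degrees of freedom), followed by moderated tests (eBayes without trend) and Benjamini-Hochberg adjustment over all genes at 0.05. The comparisons were celastrol against vehicle at each time, the mean of these differences, an F test for a celastrol effect that differs between times, and an F test for differences between times in vehicle mice. Gene lists of pathways and cell types, 31 in all, were tested with camera at a preset correlation between genes of 0.01, with adjustment over the lists of a comparison; 30 had the minimum of 5 measured members. Camera with an estimated correlation and fry served as alternatives. Counts of members adjusted over the list alone are given beside those over all genes. Measures per array were compared by exact permutation tests, 2-sided, and adjusted over the 6 tests of the family.

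The groups, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. Genes named are those past 0.05 with the largest differences, filled up to 10 per direction and time by the smallest p among genes in the upper levels (given as values that did not pass), the 10 genes of smallest p for each F test, a fixed set of leptin, neuropeptide, stress and inflammation genes, and up to 4 members of each list. Cd300c2, the last of the 11 genes of its F test, and the list of 1196 sensory receptor genes were chosen after the values were seen.

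The procedure was tested on simulated data, in which 67, 67 and 66 of the genes at each time were changed by 0.25, 0.5 and 1 on the log2 scale. It recovered 50.7% of changes of 0.25, 85.1% of 0.5 and 100% of 1 at 6 h. At 1 day it recovered 55.2%, 94% and 100%, and at 4 days 46.3%, 95.5% and 100%. The simulated noise was drawn independently for each gene and array, without the differences shared over genes that the real arrays had. These rates therefore do not cover such differences.

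Gene and list results were recomputed with a robust variance trend, without the lowest tercile of genes by level, with a further quantile normalisation, with arrays centred on their medians, with the replicate number as a block, with a component of neighbouring-tissue markers as a covariate, and without each array in turn. Gene results alone were also recomputed without the genes below the median level, with array weights, with every probe set and, except for the mean effect and the celastrol effect between times, with only the groups compared. Chosen after the data were examined were each array's SD over genes or the pituitary hormone mean as a covariate, leaving out the 4 vehicle arrays with Prl above 9, all vehicle arrays as the control at 1 day, and an exact test of list means per array.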

Results

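Hypothalamic RNA of male db/db mice, which lack functional leptin receptor signalling and become obese and diabetic, was measured on 23 expression microarrays. The animals had been injected intraperitoneally with celastrol, a plant triterpenoid that lowers food intake in obese mice, or with DMSO as the vehicle. Tissue was taken at 6 h, 1 day or 4 days. There were 4 vehicle arrays at each time, 3 celastrol arrays at 6 h, and 4 celastrol arrays each at 1 day and 4 days. The labels call the arrays of a group biological replicates. The p-values of limma, fry and the exact tests measure the spread between these samples. Those of camera with the preset correlation compare a list's genes with the other genes and rest on the spread over genes. Median log2 expression per array lay between 8.57 and 8.64. The number of arrays limits the precision: the 95% confidence interval of a celastrol difference reached, for the median gene, 0.146 on the log2 scale to either side at 6 h and 0.136 at both later times. Each comparison set celastrol against the vehicle group of the same time, to ask which hypothalamic transcripts the drug changed in animals without leptin signalling.

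After 1 day, 3 genes rose with celastrol and 0 fell. Lcn2, which encodes the iron-binding acute-phase protein lipocalin 2, stood at 7.84 ± 0.655 (SD, n = 4) with celastrol and at 6.48 ± 0.0182 (SD, n = 4) with vehicle, a 2.57-fold rise (log2 difference 1.36 ± 0.226 SE, limma, adjusted p = 0.0413). Scgb3a1, which encodes a small secreted protein of the secretoglobin family, rose 2.06-fold, from 7.86 ± 0.116 to 8.90 ± 0.462 (SD, n = 4 each; log2 difference 1.04 ± 0.158 SE, limma, adjusted p = 0.0205). Galnt15, an enzyme that starts O-linked glycosylation, rose 1.29-fold, from 7.73 ± 0.0635 to 8.10 ± 0.116 (SD, n = 4 each; log2 difference 0.37 ± 0.0635 SE, limma, adjusted p = 0.0482). For each of the 3 genes, all 4 celastrol arrays lay above all 4 vehicle arrays.

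Next in rank, and not past the threshold, were Lrg1, an acute-phase glycoprotein (log2 difference 0.63 ± 0.113 SE), and Ch25h, cholesterol 25-hydroxylase of innate immunity (0.79 ± 0.144 SE), each with an adjusted p of 0.0595 and with 4 of 4 celastrol arrays above all vehicle arrays. Among genes with lower values that did not pass were Kitl, the ligand of the receptor Kit (-0.39, adjusted p = 0.0872), the chemokine gene Cxcl12 (-0.33, adjusted p = 0.101) and the interleukin-10 receptor chain Il10rb (-0.28, adjusted p = 0.111). Il1b, which encodes interleukin-1 beta, differed by 0.32 (adjusted p = 0.214). Socs3, a feedback inhibitor of leptin and cytokine signalling, differed by 0.17 (adjusted p = 0.41), and the leptin receptor gene Lepr by -0.06 (adjusted p = 0.808). The appetite peptide genes Npy, Pomc and Cartpt differed by 0.13, 0.27 and 0.10 and the heat shock gene Hspa1a by -0.0028, none of which passed.

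Inflammatory and hormone-response lists rose as groups at 1 day, 3 in all. Of 22 measured NF-kB target and inflammatory genes, 18 were higher, with a median log2 difference of 0.153 (camera, adjusted p = 1.05e-05; adjusted p = 0.09 with an estimated correlation). In this list 9 members passed when adjusted over the list alone and 0 over all genes; examples are Ch25h, the NF-kB inhibitor Nfkbia (0.33), Tnfaip2 (0.25) and the adhesion molecule Icam1 (0.23). Of 22 acute-phase and JAK-STAT3 targets, 17 were higher, with a median of 0.101 (adjusted p = 0.000559; adjusted p = 0.2 with an estimated correlation). There 5 passed adjusted over the list alone and 1, Lcn2, over all genes; the oncostatin M receptor Osmr (0.51) and the interleukin-4 receptor Il4ra (0.22) are further examples. Of 23 glucocorticoid response genes, 18 were higher, with a median of 0.148 (adjusted p = 3.07e-05; adjusted p = 0.48 with an estimated correlation). There 7 passed adjusted over the list alone, with Plin4 (0.43) and Tmem252 (0.49) as examples; this list shares Lcn2 and Nfkbia with the other lists. The classic glucocorticoid target Fkbp5 differed by 0.14 (adjusted p = 0.526). By fry, which asks whether a list's genes move one way on balance, the NF-kB list (adjusted p = 0.0046) and the acute-phase list (adjusted p = 0.012) passed and the glucocorticoid list (adjusted p = 0.086) did not. Over the 17 measured interleukin-1 family genes the median was 0.0679 (adjusted p = 0.125).

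Lower as groups at 1 day were 4 lists. Of 21 cholesterol and fatty acid synthesis genes, 19 were lower, with a median of -0.0631 (adjusted p = 0.000127; adjusted p = 0.25 with an estimated correlation); 0 passed adjusted over the list alone, and Lss (-0.16) and Idi1 (-0.23), enzymes of sterol synthesis, are examples. Of 19 oligodendrocyte and myelin markers, 17 were lower, with a median of -0.0765 (adjusted p = 0.000934; adjusted p = 0.48 with an estimated correlation and 0.223 against all vehicle groups); 0 passed adjusted over the list alone, and Opalin (-0.29) and Ugt8a (-0.21) had low values. Of 14 endothelial markers, 10 were lower, with a median of -0.115 (adjusted p = 0.033; adjusted p = 0.48 with an estimated correlation). Its members went both ways: adjusted over the list alone, 3 were lower, among them Tek (-0.24) and Emcn (-0.27), and 2 were higher, Vwf (0.23) and the glucose transporter Slc2a1 (0.16). Thalamus markers, which tell of neighbouring tissue in a dissection, had a median of -0.112 with 11 of 14 lower (adjusted p = 0.033; adjusted p = 0.64 with an estimated correlation). Peripheral leukocyte markers did not pass (median 0.0656, adjusted p = 0.0565), although Cd8a (0.25) and S100a8 (0.27) passed adjusted over the list alone. The other hypothalamic neuropeptides had a median of 0.0652 and a mean of 0.00121 (adjusted p = 0.429).

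At 1 day, 2338 of 18702 genes had an unadjusted p under 0.05, 1555 higher and 783 lower, where chance gives 935. The 1-day vehicle arrays lay below the other vehicle groups for Lcn2 (6.48 against 7.27 at 6 h and 7.10 at 4 days) and Galnt15 (7.73 against 7.97 and 8.02), while Scgb3a1 stood at 7.86 against 7.98 and 7.90. They also lay low for the 65 members of the NF-kB, acute-phase and glucocorticoid lists (median -0.076), and against the vehicle arrays of 6 h and 4 days the celastrol median of these genes was 0.0433 in place of 0.142, 30.4% of its size. With all vehicle groups as the control, the Lcn2 and Galnt15 calls were lost (log2 differences 0.89 and 0.19), and Scgb3a1 kept its call. The difference of the celastrol effect between times did not pass for Lcn2 (adjusted p = 0.0911), Scgb3a1 (adjusted p = 0.092) or Galnt15 (adjusted p = 0.0677). The log2 values of the 1-day celastrol arrays spread less over genes than those of vehicle (SD 1.915 against 1.948, exact permutation test, 2-sided p = 0.0286, 0.0858 after adjustment). The calls of Lcn2, Scgb3a1 and Galnt15 were lost when single arrays were left out (highest adjusted p = 0.178, 0.162 and 0.252). When the 4 vehicle arrays with Prl above 9 were left out 0 genes passed, against 406 with array weights. Without the genes below the median level 0 passed too, but that filter removed all 3 genes from the test. The endothelial and thalamus lists were lost without replicate 1 or 4 of celastrol or replicate 2 of vehicle, the endothelial list also without replicate 4 of vehicle or after a further quantile normalization (adjusted p = 0.0936) and the thalamus list also without replicate 3 of the 6-h vehicle group (highest adjusted p = 0.0991 and 0.521 over all arrays left out in turn), and without the lowest tercile of genes (adjusted p = 0.134 and 0.126), and these and the cholesterol list were lost with each array's spread as a covariate.

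**Figure D1:**
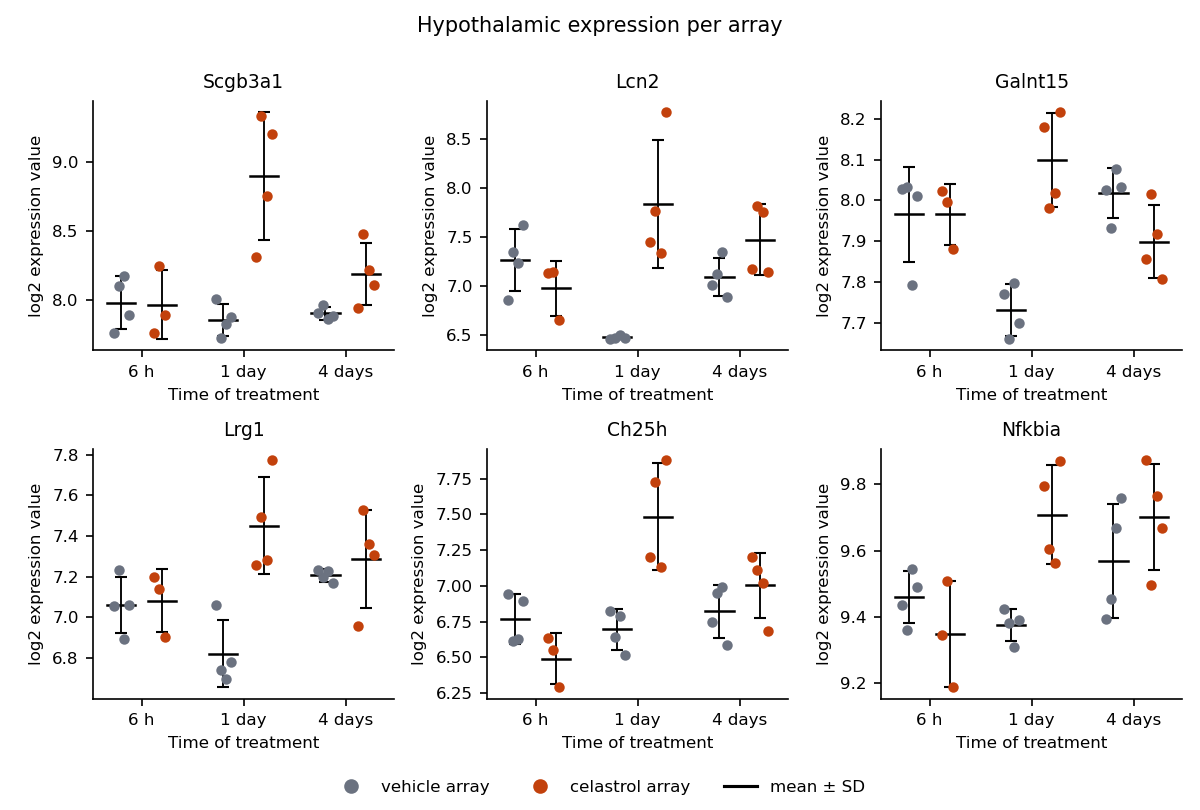
Log2 expression of 6 genes in each of the 23 arrays, by time of treatment (points), with group mean and SD (bars). At 1 day, all 4 celastrol arrays lay above all 4 vehicle arrays for Scgb3a1, Lcn2 and Galnt15, the 3 genes that passed, and for Lrg1, Ch25h and Nfkbia, which did not pass.

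At 6 h, no gene passed (limma, 0 of 18702). Retsat, a retinol saturase, stood at 8.75 ± 0.0664 (SD, n = 3) with celastrol and at 9.08 ± 0.0587 (SD, n = 4) with vehicle, a log2 difference of -0.33 ± 0.0634 SE (limma, adjusted p = 0.117). Cyp2d40, a cytochrome P450 gene, stood at 8.31 ± 0.0929 against 7.72 ± 0.137 (SD), a difference of 0.59 ± 0.124 SE (adjusted p = 0.148). Lower values that did not pass were also found for Tomm22, part of the mitochondrial protein import pore (-0.29), the mitochondrial enzyme Suclg2 (-0.32), and Cd59a, an inhibitor of complement (-0.40), each with an adjusted p of 0.156. The tyrosine phosphatase gene Ptpn2 differed by -0.25 (adjusted p = 0.228), Lepr by -0.25 (adjusted p = 0.249), Socs3 by 0.18 (adjusted p = 0.355) and Lcn2 by -0.29 (adjusted p = 0.58). Differences for Pomc (-0.51 ± 0.514 SE), Npy (-0.13) and Cartpt (0.02) did not pass. The stress genes Hspa1a (-0.13), Hmox1 (-0.12) and Hspa5 (0.0041), the phosphatase gene Ptpn1 (-0.10) and the activity-induced genes Fos (0.17) and Nr4a1 (-0.02) did not pass either.

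Genes of protein turnover and respiration were lower as groups with celastrol than with vehicle at 6 h. Of 31 proteasome subunits, 30 were lower, with a median log2 difference of -0.0987 (camera, adjusted p = 2.69e-06; adjusted p = 0.78 with an estimated correlation); Psmd13 (-0.16) and Psma4 (-0.19) are examples. All 30 oxidative phosphorylation genes were lower, with a median of -0.106 (adjusted p = 2.69e-06; adjusted p = 0.78 with an estimated correlation), among them Ndufv1 (-0.13), Ndufs1 (-0.15) and Uqcrc2 (-0.11). Of 22 ribosomal protein genes, 21 were lower, with a median of -0.0955 (adjusted p = 0.00194; adjusted p = 0.78 with an estimated correlation), Rpl22 by -0.22. In these 3 lists, 0 members passed adjusted over the list alone. Of 23 glucocorticoid response genes, 19 were lower, with a median of -0.0835 (adjusted p = 0.00419; adjusted p = 0.78 with an estimated correlation); 0 passed adjusted over the list alone, and Sgk1 (-0.36), Errfi1 (-0.21) and Fkbp5 (-0.21) had low values. Of 20 heat shock response genes, 17 were lower, with a median of -0.0798 (adjusted p = 0.00534; adjusted p = 0.72 with an estimated correlation). There 1, the chaperone cofactor Chordc1 (-0.22), passed adjusted over the list alone; Cacybp (-0.16) and Ahsa1 (-0.15) did not. Peripheral leukocyte markers rose as a group, with 10 of 15 higher and a median of 0.0725 (adjusted p = 0.0451; adjusted p = 0.78 with an estimated correlation). There 3 passed adjusted over the list alone, among them the monocyte chemokine receptor Ccr2 (0.32) and the T-cell gene Cd3e (0.23). For the leukocyte list, 68.4% of 10000 random lists matched on mean level had a median as high. The rise of its median thus did not exceed that of genes of like level. Of 17 interleukin-1 family genes, 2 passed adjusted over the list alone, the decoy receptor Il1r2 (0.34) and Il1b (0.33), while the list had a median of -0.0237 (adjusted p = 0.673).

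At 6 h, 2763 genes had an unadjusted p under 0.05, 1600 higher and 1163 lower, where chance gives 935. The celastrol arrays spread less over genes than the vehicle arrays (SD 1.889 against 1.93, exact permutation test, 2-sided p = 0.0286, 0.0858 after adjustment), and 883 of 1196 odorant, vomeronasal and other sensory receptor genes, a list chosen after the data were seen, were higher with celastrol (median 0.0704). The 6-h vehicle arrays stood above the other vehicle groups for all 5 lists that were lower with celastrol. For oxidative phosphorylation the mean was 11.46 against 11.37 at 1 day and 11.3 at 4 days, and 11.34 with celastrol at 6 h. For the proteasome it was 10.86 against 10.79 and 10.75, and 10.75 with celastrol. For ribosomal proteins it was 11.43 against 11.36 and 11.37, and 11.33 with celastrol. For heat shock it was 10.79 against 10.76 and 10.68, and 10.71 with celastrol. For the glucocorticoid response it was 9.664 against 9.555 and 9.651, and 9.563 with celastrol. Without replicate 3 of the vehicle group, the proteasome (adjusted p = 0.0811), oxidative phosphorylation (adjusted p = 0.313) and ribosomal (adjusted p = 0.854) lists no longer passed. The heat shock list was lost without replicate 1 of celastrol (adjusted p = 0.0716) or the lowest tercile of genes (adjusted p = 0.0811), the glucocorticoid list without replicate 3 of celastrol (adjusted p = 0.0918) or without the vehicle arrays with Prl above 9 (adjusted p = 0.0528) and the leukocyte list in most settings and when any 1 of 7 arrays was left out; a further quantile normalization ended the heat shock, ribosomal and leukocyte calls, and each array's spread as a covariate the proteasome, heat shock and leukocyte calls.

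At 4 days, no gene passed (limma, 0 of 18702). The insulin-like growth factor binding protein gene Igfbp2 stood at 7.77 ± 0.119 (SD, n = 4) with celastrol and at 8.25 ± 0.292 (SD, n = 4) with vehicle, a log2 difference of -0.48 ± 0.102 SE (limma, adjusted p = 0.248). Serpind1, which encodes heparin cofactor II, differed by -0.71 ± 0.174 SE and the dicarboxylate transporter gene Slc13a3 by -0.62 ± 0.153 SE (adjusted p = 0.306 each). Hs3st6, a heparan sulfate sulfotransferase gene, differed by -0.26 (adjusted p = 0.139) and Scarf2 by -0.21 (adjusted p = 0.285), with 4 of 4 celastrol arrays below all vehicle arrays for both. Kcnj13, a potassium channel gene of choroid plexus, differed by -1.02 ± 0.284 SE (adjusted p = 0.326). Higher values that did not pass belonged to Gpr50, an orphan receptor of tanycytes (0.28, adjusted p = 0.308), and Zc3h12c (0.17, adjusted p = 0.306). Differences for Lepr (0.14), Npy (0.17), Cartpt (0.14), Pomc (-0.67 ± 0.476 SE), Socs3 (-0.06), Lcn2 (0.38) and Hspa1a (-0.15) did not pass.

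Mural cell and perivascular fibroblast markers fell as a group at 4 days. Of 18, 16 were lower, with a median log2 difference of -0.119 (camera, adjusted p = 2.83e-05; adjusted p = 0.52 with an estimated correlation). There 4 passed adjusted over the list alone: Igfbp2, the GABA transporter gene Slc6a13 (-0.78), the growth factor gene Igf2 (-0.64) and the matrix protein gene Vtn (-0.28). Thalamus markers fell, with 13 of 14 lower and a median of -0.169 (adjusted p = 0.00978; adjusted p = 0.99 with an estimated correlation), and 0 passed adjusted over the list alone. Peripheral leukocyte markers fell, with 10 of 15 lower and a median of -0.0829 (adjusted p = 0.0367; adjusted p = 0.7 with an estimated correlation); Cd8a (-0.24) and Cd3e (-0.23) passed adjusted over the list alone. Neuropeptide lists rose as groups. Of 21 feeding circuit genes, 19 were higher, with a median of 0.0606 (adjusted p = 0.0148; adjusted p = 0.43 with an estimated correlation), and of 28 other hypothalamic neuropeptides and receptors, 21 were higher, with a median of 0.0611 (adjusted p = 0.00978; adjusted p = 0.52 with an estimated correlation). In both, 0 passed adjusted over the list alone; Pdyn, the prodynorphin gene (0.18), and Hdc, the histamine-forming enzyme gene (0.23), are examples. Pituitary markers had a median of -0.15 (adjusted p = 0.122).

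At 4 days, 1364 genes had an unadjusted p under 0.05, 510 higher and 854 lower, where chance gives 935. The 4-day vehicle arrays stood above the other vehicle groups for the mural and fibroblast list (mean 9.019 against 8.762 at 6 h and 8.696 at 1 day, and 8.81 with celastrol at 4 days) and for the leukocyte list (6.629 against 6.532 and 6.457, and 6.557 with celastrol). Without replicate 4 of the vehicle group, 39 genes passed and the thalamus list did not (adjusted p = 0.827; it was also lost without replicate 3 of celastrol). The 2 neuropeptide lists were lost without replicate 1 or 3 of celastrol, the leukocyte list when any 1 of 5 arrays was left out, and all 3 with each array's spread as a covariate; the leukocyte list was also lost with the neighbouring-tissue component (adjusted p = 0.108) or the pituitary hormone mean (adjusted p = 0.104) as a covariate and after a further quantile normalization (adjusted p = 0.191).

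**Figure D2:**
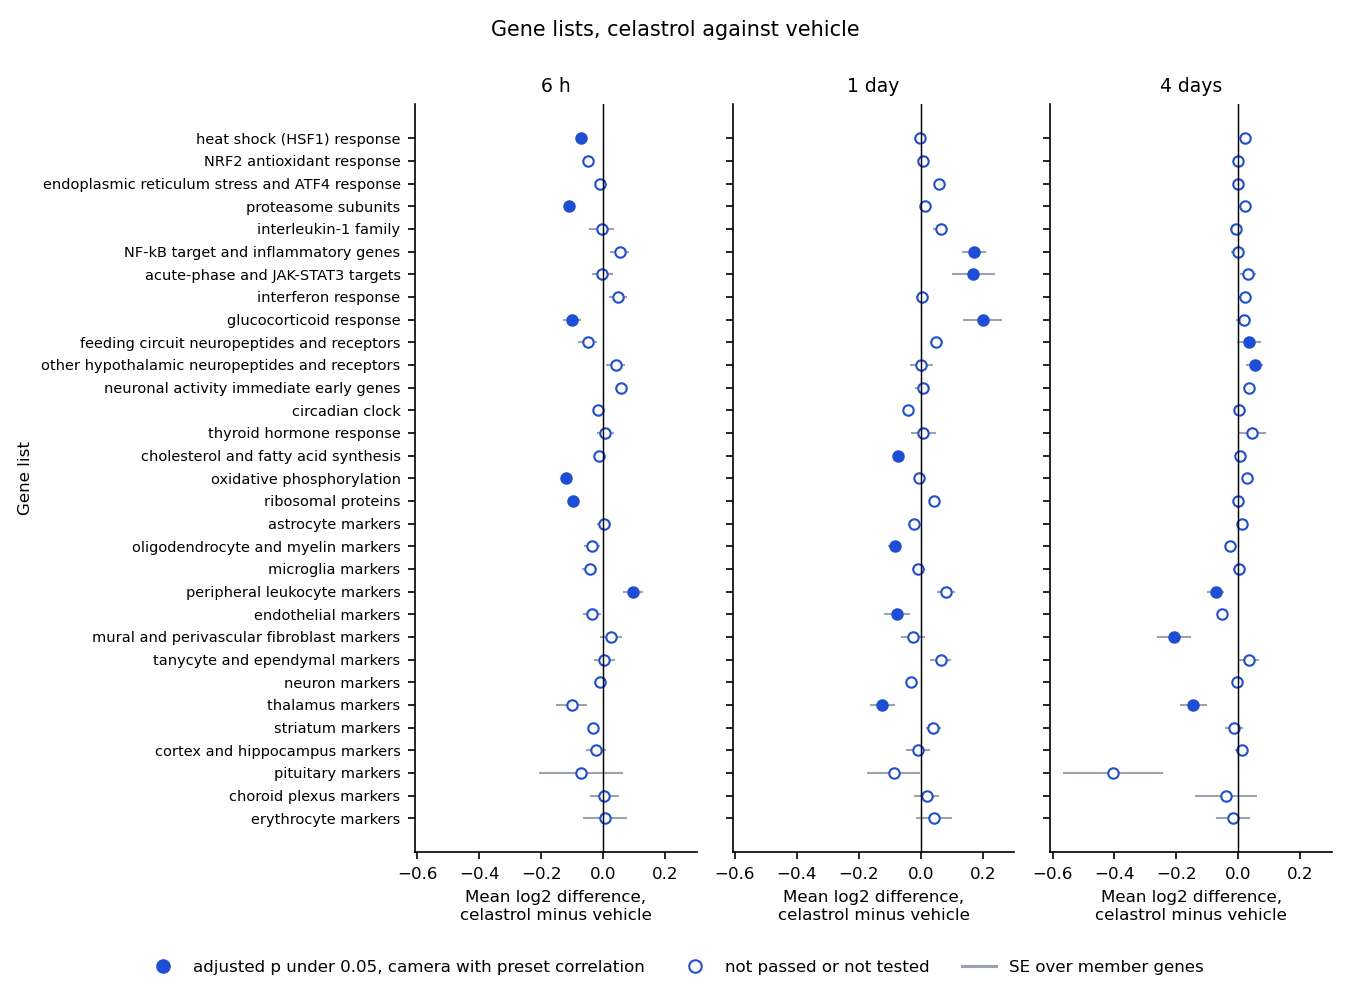
Mean log2 difference of celastrol minus vehicle for each of the 31 gene lists at 6 h, 1 day and 4 days (points), with the SE over member genes (lines); filled points passed camera with the preset correlation. The number of filled points is 6 at 6 h, 7 at 1 day and 5 at 4 days.

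Averaged over the 3 times, no gene passed (limma, 0 of 18702; lowest adjusted p = 0.0775), and 2530 had an unadjusted p under 0.05, 1548 higher and 982 lower. The NF-kB list rose (18 of 22 higher, median 0.0811, adjusted p = 0.00232), as did the acute-phase list (17 of 22 higher, median 0.0531, adjusted p = 0.0194), by camera with the preset correlation. With an estimated correlation, no list passed for this mean (0.56 and 0.62 for these lists, the lowest adjusted p being 0.56), and by fry 0 lists passed. The thalamus (adjusted p = 0.00232), oligodendrocyte (adjusted p = 0.00738), endothelial (adjusted p = 0.00885), oxidative phosphorylation (adjusted p = 0.0194), mural and fibroblast (adjusted p = 0.0235), proteasome (adjusted p = 0.0388) and cholesterol (adjusted p = 0.0438) lists fell. Some of these falls came mainly from a single time. At 6 h, 1 day and 4 days the mean difference was -0.112, 0.0148 and 0.0206 for the proteasome. For oxidative phosphorylation it was -0.121, -0.00447 and 0.028. For cholesterol it was -0.0137, -0.0742 and 0.00532, and for mural and fibroblast markers 0.0247, -0.024 and -0.209. Thalamus, oligodendrocyte and endothelial means were negative at all 3 times. The NF-kB and acute-phase rises came mainly from 1 day. With each array's spread as a covariate, the NF-kB (adjusted p = 0.089), oligodendrocyte (0.1), endothelial (0.15), oxidative phosphorylation (0.66), proteasome (0.75) and cholesterol (0.97) lists no longer passed. Across genes, which are not independent replicates, the celastrol differences at 6 h and 1 day had a Pearson correlation of 0.477, those at 6 h and 4 days of -0.178, and those at 1 day and 4 days of -0.159. The differences also varied with the mean level of genes, with Spearman correlations of -0.391, -0.384 and 0.229 at 6 h, 1 day and 4 days. A shared drug response therefore cannot be told apart from this relation to level.

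The celastrol effect differed between times for 11 genes (limma F test over 2 contrasts; 2440 with an unadjusted p under 0.05). All 11 had a positive difference at 6 h and 1 day and a negative difference at 4 days. Slc12a3, the thiazide-sensitive sodium chloride transporter gene, differed by 0.35 at 6 h, 0.31 at 1 day and -0.17 at 4 days, and the cytokine gene Il25 by 0.17, 0.21 and -0.32 (adjusted p = 0.0231 each). Tmprss13, Hs3st6 and Rnf207 had the same adjusted p, and Grk1, Cilp2, Dhrs13os, Scarf2, Olfr1393 and Cd300c2 lay between 0.0292 and 0.048. The 4-day effect minus the 1-day effect was -0.48 for Slc12a3 and -0.66 for Olfr1393. Vehicle mice alone rose in both genes between these times (limma F test between times, adjusted p = 0.000334 and 0.000184). For these genes a changing drug effect and a moving vehicle group cannot be told apart. Among the lists, the 1-day effect lay above the 6-h effect for 11 lists and below it for 1 at 0.05 with the preset correlation, most clearly for the glucocorticoid response (adjusted p = 6.57e-13), proteasome (adjusted p = 2.35e-07), ribosomal (adjusted p = 3.63e-06) and oxidative phosphorylation (adjusted p = 5.02e-06) lists; with an estimated correlation these 4 had adjusted p of 0.21, 0.32, 0.32 and 0.45, and no list passed. In vehicle mice alone these 4 lists fell from 6 h to 1 day, with medians of -0.0929, -0.0744, -0.0701 and -0.0757. Their adjusted p by camera was 0.0358, 0.0208, 0.0314 and 0.00418, and 0.74 for each with an estimated correlation. A changing drug effect and a moving vehicle group cannot be told apart for these lists either. The 4-day effect lay below the 1-day effect for the NF-kB (adjusted p = 0.00347, and 0.54 with an estimated correlation) and glucocorticoid (adjusted p = 0.00973, and 0.82) lists. In vehicle mice alone the NF-kB list rose from 1 day to 4 days, with 21 of 22 genes higher and a median of 0.16. Its adjusted p by camera was 0.0233, and 0.56 with an estimated correlation. The NF-kB mean went from 7.395 to 7.532 with vehicle and from 7.567 to 7.53 with celastrol. The glucocorticoid mean went from 9.555 to 9.651 with vehicle and from 9.753 to 9.668 with celastrol. The 11 genes were lost with each array's spread as a covariate and after a further quantile normalization, and 118 passed without replicate 4 of celastrol at 4 days.

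Vehicle mice alone differed between times in 1651 genes (limma F test; 5321 with an unadjusted p under 0.05), which gives the background against which the drug was tested. Between 4 days and 1 day, 1600 genes were higher and 603 lower; between 4 days and 6 h, 357 were higher and 375 lower, and between 1 day and 6 h, 0 passed (1999 with an unadjusted p under 0.05). Chordc1 fell from 10.27 ± 0.102 to 9.78 ± 0.0509 (SD, n = 4 each) between 1 day and 4 days, a log2 difference of -0.49 ± 0.0547 SE, and the deubiquitinase gene Mindy2 fell from 11.65 to 11.12 (limma F test, adjusted p = 0.000137 each). Hacd2 (-0.26), Ugcg (-0.36), Naa20 (-0.28), Septin7 (-0.37) and the peroxiredoxin gene Prdx2 (-0.29) fell, and Slc12a3 (0.49), Olfr1393 (0.78) and Olfr522 (0.47) rose. The Naa20 difference ranged from -0.3049 to -0.0663 over the 13 alternative settings, all of which kept its call. Mural and fibroblast markers rose from 1 day to 4 days, 17 of 18 being higher (camera, adjusted p = 0.00047; adjusted p = 0.56 with an estimated correlation). Of these, 12 passed adjusted over the list alone and 5 over all genes, with Igfbp2 (0.72), Igf2 (0.86) and Slc6a13 (0.94) as examples. Peripheral leukocyte markers rose, 15 of 15 being higher (adjusted p = 0.00854, and 0.56 with an estimated correlation), with Cd8a (0.36) past the threshold over all genes. Of random lists matched to the leukocyte list on mean level, 61.3% had a median as high. The heat shock list fell (adjusted p = 0.00047; adjusted p = 0.47 with an estimated correlation). Il1b (0.36, adjusted p = 0.0234) and Kcnj13 (1.41, adjusted p = 0.00475) rose. The spread of log2 values was narrower at 4 days than at 1 day (SD 1.895 against 1.948, exact permutation test, 2-sided p = 0.0286), and with that spread as a covariate 2 genes passed.

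Pituitary hormone genes varied widely between arrays. Over all 23 arrays Gh ranged over 39.8-fold and Prl over 42.5-fold, and 4 arrays, all of them vehicle, had Prl above 9. A difference between celastrol and vehicle in the mean of the pituitary hormone genes was not detected (exact permutation tests, 2-sided, p = 0.886 at 6 h, 0.657 at 1 day and 0.114 at 4 days). Vehicle replicate 3 at 6 h correlated least with the other arrays (median r across genes 0.993, against 0.9957 or more for the rest). Of the erythrocyte markers, 4 were measured, too few for a test, with medians of 0.0154, -0.00949 and -0.0425 at the 3 times.

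**Figure D3:**
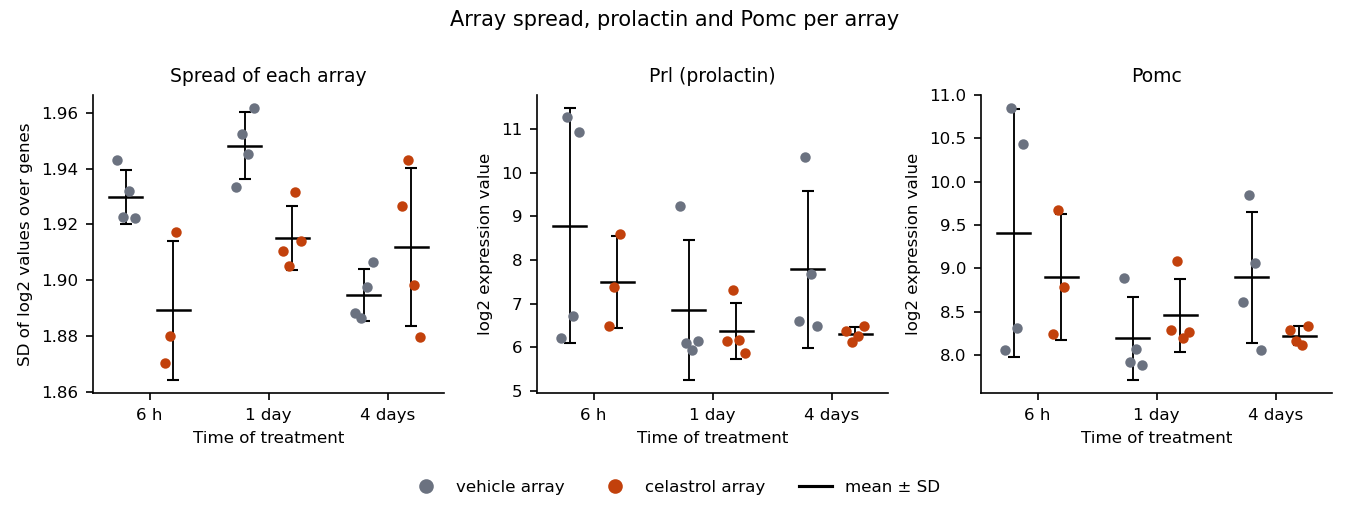
Spread of log2 values over genes, Prl and Pomc in each array by time of treatment (points), with group mean and SD (bars). The spread had means of 1.93, 1.948 and 1.895 in vehicle mice and 1.889, 1.915 and 1.912 in celastrol mice at 6 h, 1 day and 4 days, and Pomc ranged from 7.89 to 10.84 over the arrays.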

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

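The tests of array spread, pituitary tissue, the low vehicle group, leukocytes and the single vehicle array were chosen only after the result was seen; the splits of the samples, the celastrol array left out and the random lists were not.

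The NF-kB, acute-phase and glucocorticoid lists were higher with celastrol at 1 day, with a median log2 difference of 0.142 over their 65 members, but none of the 3 passed with an estimated correlation (adjusted p = 0.09, 0.2 and 0.48) and the glucocorticoid list did not pass by fry (adjusted p = 0.086). By camera with the preset correlation, all 3 stayed past the threshold with each array's spread as a covariate (highest adjusted p = 0.00359). They also did without replicate 4 of celastrol, the array with the highest values (highest adjusted p = 0.00442). That test rests on the spread over genes and not between arrays, so it cannot exclude either explanation. Averaged over the 65 members, each celastrol array lay above the vehicle mean, by 0.0872 to 0.246. The higher values were thus not confined to replicate 4. Leukocyte markers had a median of 0.0656 (SE over genes 0.0293), below that of the lists. Their mean level at 1 day (6.538 with celastrol, 6.457 with vehicle) lay below the lower quartile of genes on each of these arrays. Of 15 markers, which are of several cell types, 2 passed as higher adjusted over the list alone. The comparison of medians therefore cannot decide on blood leukocytes. The 1-day vehicle arrays lay low for these genes (median -0.076 against the other vehicle arrays), and against the vehicle arrays of 6 h and 4 days the celastrol median was 0.0433 (SE 0.0204), 30.4% of its value, with 45 of 65 members higher; against all vehicle arrays, the 1-day ones included, all 3 lists stayed past the threshold with the preset correlation. A drug response and a low vehicle group therefore cannot be told apart, since time and vehicle group are confounded in that comparison, both may contribute, and chance is not excluded for the number of lists (10 of 35 splits).

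The proteasome and oxidative phosphorylation lists were lower with celastrol at 6 h by camera with the preset correlation and did not pass with an estimated one (adjusted p = 0.78 for both). Random lists matched on mean level gave medians as low in 0% of 10000 draws for both, which argues against expression level alone. With each array's spread as a covariate, the proteasome list no longer passed (adjusted p = 0.211; median -0.0987 before and -0.0364 after, SE over genes 0.0122 and 0.0115), while the oxidative phosphorylation list did (adjusted p = 0.015; median -0.106 before and -0.0684 after). Without replicate 3 of vehicle, which correlated least with the other arrays, neither passed (lowest adjusted p = 0.0811; medians -0.0422 ± 0.00705 SE and -0.0111 ± 0.00784 SE). A candidate explanation is therefore high values in that 1 vehicle array, a drug effect on these genes stays open, and chance is not excluded for the number of lists (16 of 35 splits).

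Vehicle mice differed between times in 1651 genes. Pituitary tissue does not account for it, since 1381 genes passed with the pituitary hormone mean as a covariate. With each array's spread as a covariate, 2 genes passed; the median size of the difference between 4 days and 1 day fell from 0.26 to 0.152 on the log2 scale, 58.4% of its size, and the median standard error rose to 136% of its own. The count thus ended through both a smaller difference and a larger error, and since the spread differs between the times the covariate and the times cannot be told apart. Time of day, repeated injection and the handling of arrays at each time may each contribute, and none was tested.

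Other splits of the same arrays gave the following. At 1 day, only the real split gave as many as the 2338 genes with an unadjusted p under 0.05 (1 of 35 splits, highest other 1615). This argues against chance but cannot exclude it, since the share cannot fall below 1 of 35 and the split tests were not adjusted for their number. For the 3 genes past the adjusted threshold the share was also 1 of 35 (highest other 0). That count is small, and other splits at 4 days gave up to 10 where the real one gave 0. Chance cannot be excluded for the 7 lists (10 of 35, highest other 13). At 6 h it cannot be excluded for the 2763 genes (5 of 35, highest other 3293) or the 6 lists (16 of 35, highest other 11), nor at 4 days for the 1364 genes (10 of 35, highest other 2123) or the 5 lists (9 of 35, highest other 8). For the mean over the times, 2 of 100 draws gave as many as the 2530 genes (highest other 2681), which argues against chance without excluding it. For the 9 lists chance cannot be excluded (15 of 100, highest other 17). Only the real grouping gave as many as the 11 genes whose effect differed between times (1 of 100, highest other 1). The same held for the 1651 genes of vehicle mice (1 of 100, highest other 184). Both counts argue against chance.

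The celastrol effect differed between times, by the limma F test, for Tmprss13, Hs3st6, Il25, Slc12a3 and Rnf207 (adjusted p = 0.0231 each), Grk1 (adjusted p = 0.0292), Cilp2 (adjusted p = 0.0347), Dhrs13os (adjusted p = 0.0384), Scarf2 (adjusted p = 0.0406), and Olfr1393 and Cd300c2 (adjusted p = 0.048 each). By camera with the preset correlation, and in no case with an estimated one (adjusted p from 0.21 to 0.45), the 1-day effect lay above the 6-h effect for the lists of heat shock (adjusted p = 0.0381), endoplasmic reticulum stress and ATF4 (0.0104), proteasome (2.35e-07), interleukin-1 family (0.0381), NF-kB (0.0141), acute-phase (0.00433), glucocorticoid (6.57e-13), feeding circuit (0.0252), oxidative phosphorylation (5.02e-06), ribosomal (3.63e-06) and striatum genes (0.0447), and below it for cholesterol synthesis (0.0057). With the preset correlation only (0.55 to 0.93 with an estimated one), the 4-day effect lay above the 6-h effect for heat shock (0.00951), proteasome (5.91e-05), glucocorticoid (0.0229), feeding circuit (0.0229), oxidative phosphorylation (5.91e-05) and ribosomal genes (0.0229), and below it for leukocyte (0.00767) and mural and fibroblast markers (0.0116). Likewise (0.54 to 0.82 with an estimated one), the 4-day effect lay below the 1-day effect for NF-kB (0.00347), glucocorticoid (0.00973) and leukocyte genes (0.00973) and above it for cholesterol synthesis (0.00973). Vehicle mice alone also moved between times in several of these lists. For those lists a changing drug effect and a moving vehicle group cannot be told apart. Among 3264 probe sets outside the gene comparisons, 1 (10563728, with no gene in the annotation table) was higher with celastrol at 6 h, at 7.43 against 6.94, a 1.41-fold difference (log2 0.49 ± 0.0797 SE, limma, adjusted p = 0.0146), and 0 passed at 1 day or 4 days (limma; 380 and 237 with an unadjusted p under 0.05). For 3 others the 4-day effect differed from the 1-day effect: 10360542 (log2 0.42, adjusted p = 0.0339), 10436658 (0.51, adjusted p = 0.0339) and 10561706 (-0.42, adjusted p = 0.0374).

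Single arrays stood apart from the other 3 of their group in 40 of 505 tests of a gene or array measure, where chance gives about 1 in 20, or 25; the values are the gap to the nearest array as a fraction of the group's range. In vehicle mice at 6 h, replicate 1 was low for Il1r2 (0.921), replicate 2 low for Sgk1 (0.856), replicate 3 high for Psma4 (0.917) and Idi1 (0.892) and low for Galnt15 (0.9) and for its median correlation with the other arrays (0.932), and replicate 4 high for Icam1 (0.875) and low for Prdx2 (0.868). In vehicle mice at 1 day, replicate 1 was high for Fkbp5 (0.914), Gh (0.891) and Prl (0.944) and low for Ndufs1 (0.843), replicate 2 low for Tmem252 (0.947) and Hdc (0.944), replicate 3 low for Chordc1 (0.884) and replicate 4 high for Cartpt (0.883). In vehicle mice at 4 days, replicate 2 was high for Gh (0.864), replicate 3 high for Vwf (0.858) and low for Hdc (0.854), and replicate 4 low for Slc6a13 (0.833), Serpind1 (0.926), Socs3 (0.839) and Cd300c2 (0.832). With celastrol at 1 day, replicate 1 was low for Retsat (0.881), replicate 2 high for Pomc (0.897), Hmox1 (0.925), Gh (0.842) and the pituitary hormone mean (0.93), replicate 3 low for Lepr (0.88), and replicate 4 high for Cartpt (0.945) and low for Emcn (0.841). With celastrol at 4 days, replicate 1 was low for Il1r2 (0.952) and high for Grk1 (0.869), replicate 2 high for Pdyn (0.884) and low for Tbxa2r (0.836) and Olfr522 (0.892), replicate 3 high for Socs3 (0.946), and replicate 4 low for Cacybp (0.84), Hacd2 (0.834) and its median correlation (0.852). Celastrol at 6 h, with 3 arrays, was not tested.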

How the results depend on the processing

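Settings chosen only after the data were seen were the array SD or the pituitary hormone mean as a covariate, leaving out the vehicle arrays with Prl above 9, all vehicle groups as control, and the exact test of list means; where not said otherwise, the cause of a change was not tested. Of the 18 lists passing at the 3 times, 0 passed with an estimated correlation or by an exact test of list means per array. By fry 2 passed (NF-kB and acute-phase at 1 day, both higher). The smallest exact p, 0.0286, hardly allows a pass over 30 lists. At 1 day 4 lists reached it, all of them higher (glucocorticoid 0.0571). They were these 2, the interleukin-1 family list, and the endoplasmic reticulum stress and ATF4 list. At 6 h and 4 days, however, 0 had p under 0.05. Other settings gave 15 to 20. The 15 with the array SD as a covariate hold 9 of the 18 and 6 new calls. Among them at 1 day were proteasome and endoplasmic reticulum stress and ATF4, both higher (adjusted p = 0.000982 and 0.00757). Single arrays left out gave 13 (without vehicle 6 h replicate 3) to 20. At 1 day, against 3 genes, 1 other gene passed with the array SD as a covariate (0 of the 3 kept) and 2 others with only the groups compared (0 kept). With all vehicle groups as control 4 passed (1 kept, Scgb3a1), and with array weights 406 (290 higher, all 3 kept). The count was 0 without the arrays with Prl above 9, 1 after quantile normalization and 0 with a robust variance trend. Without the genes below the median level it was 0, but that filter removed all 3 from the test. Leaving out single arrays gave 0 (celastrol 1 day replicates 2 and 4, vehicle 1 day replicates 2, 3 and 4) to 7 (celastrol 1 day replicate 3), and 1 without celastrol 6 h replicates 1 or 2, any vehicle array of 4 days or vehicle 6 h replicate 2. Lcn2 kept its call in 6 of 12 settings and 9 of 23 arrays left out, Scgb3a1 in 9 of 13 and 18 of 23, and Galnt15 in 2 of 13 and 4 of 23, all with their direction. At 6 h the 0 genes became 16 (10 higher) without the arrays with Prl above 9, and 0 to 2 without single arrays (2 without vehicle 6 h replicate 4, 1 without vehicle 6 h replicate 1 or celastrol 6 h replicate 3). At 4 days single arrays left out gave 0 to 39 (39 without vehicle 4 days replicate 4, 2 without celastrol 6 h replicate 3, 1 without celastrol 4 days replicate 3 or 4 or vehicle 4 days replicate 1). For the mean effect they gave 0 to 9 (9 without celastrol 4 days replicate 2 or vehicle 4 days replicate 4, 3 without vehicle 6 h replicate 2, 2 without vehicle 1 day replicate 2 or vehicle 4 days replicate 2, 1 without celastrol 1 day replicate 1). The 11 genes whose effect differed between times became 0 with the array SD or the neighbouring-tissue component as a covariate, after quantile normalization and with a robust variance trend. They became 7 with the pituitary hormone mean. Without the genes below the median level 0 passed and without the lowest tercile 5, but both filters themselves remove genes from the test. Of the 10 genes of smallest p, the median filter left only Scarf2 in the test, where it did not pass. Single arrays left out gave 0 (celastrol 1 day replicate 4, celastrol 4 days replicates 1 and 2) to 118 (celastrol 4 days replicate 4), with 19 without celastrol 1 day replicate 3 or celastrol 4 days replicate 3, 20 without celastrol 6 h replicate 3, 24 without vehicle 6 h replicate 4, 6 without vehicle 4 days replicate 2, 5 without vehicle 6 h replicate 1, 4 without vehicle 1 day replicate 4 and 3 without vehicle 4 days replicate 3. The 1651 genes of vehicle mice became 2 with the array SD as a covariate, 2491 with array weights, 852 without the genes below the median level and 710 after quantile normalization; single arrays left out gave 664 (vehicle 4 days replicate 2) to 1932 (vehicle 6 h replicate 4), with 901, 1019 and 829 without vehicle 1 day replicates 2, 3 and 4 and 865 and 747 without vehicle 4 days replicates 1 and 3. The replicate numbers do not pair the arrays: 2 of 11 pairs had correlated deviations over 0.1 (range -0.0826 to 0.188) and 2 celastrol arrays correlated best with their own number. With the number as a block, 14 genes passed at 4 days (2 higher), 1055 in vehicle mice, 0 differed between times, and the 1-day count was 3, of which 2 were the same genes. The pituitary list at 6 h turned from lower to higher without the vehicle arrays with Prl above 9 (mean log2 difference 0.6368), since that choice removes arrays high in it. With only the groups compared, 1121 genes passed in vehicle mice. This setting was not run for the mean effect or the celastrol effect between times, which use all groups. The oligodendrocyte list at 1 day was lost with all vehicle groups as control (adjusted p = 0.223) and the glucocorticoid list at 6 h without the arrays with Prl above 9 (adjusted p = 0.0528). The leukocyte call at 6 h was lost also with arrays centred (adjusted p = 0.0623), the neighbouring-tissue component (0.0518), the pituitary hormone mean (0.0519), without the arrays with Prl above 9 (0.117) and with a robust variance trend (0.054). Single lists and genes that passed kept their direction in all settings.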

Other observations

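All tests of Pomc and pituitary markers in this part were chosen only after the result was seen.

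Pomc, which encodes the precursor of melanocortins in hypothalamic neurons and of corticotropin in the pituitary, ranged from 7.89 to 10.84 over the 23 arrays, more widely than Npy (11.15 to 11.96) or Cartpt (10.05 to 10.58), which are made by neurons of the same nucleus. A candidate explanation is pituitary tissue left on some samples. Pomc correlated with the mean of the hormone genes Gh and Prl (Pearson's r = 0.904, permutation p = 1e-05, Spearman's rho = 0.825, permutation p = 1e-05, the smallest that the permutations give; adjusted over 3 genes, 3e-05 for both). The correlation held within groups (r = 0.895), in vehicle arrays (r = 0.944), in celastrol arrays (r = 0.729) and without the 2 arrays farthest from the median (r = 0.815). Npy (r = -0.363, permutation p = 0.09, adjusted p = 0.14; rho = -0.257, permutation p = 0.2) and Cartpt (r = -0.279, permutation p = 0.2; rho = -0.229, permutation p = 0.3) had no positive relation; within groups r was -0.419 for Npy and -0.0529 for Cartpt, in vehicle arrays -0.168 and -0.0162, and in celastrol arrays -0.665 and -0.463. Differences in Pomc between groups therefore may reflect dissection.

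In vehicle mice, 936 of 1196 sensory receptor genes, a list chosen after the data were seen and not tested against other genes, had higher values at 4 days than at 1 day (median log2 difference 0.111, against 0.0329 over all genes, with a Spearman correlation of -0.453 with the mean level). With celastrol their values were higher in 883 of 1196 cases at 6 h (median 0.0704) and in 809 at 1 day (median 0.0394), and in 469 at 4 days (median -0.0258). Over all genes, the Spearman correlation of the celastrol difference with the mean level was -0.391 at 6 h, -0.384 at 1 day and 0.229 at 4 days.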
